A study of Mus musculus with 2 samples.

How the data were processed

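The series holds 2 one-colour expression arrays of whole mouse lung, taken 14 days after bleomycin at 1.25 mg/kg. The labels give 1 sample from a C57BL6/N mouse and 1 from a C57BL6/N mouse overexpressing heat shock protein 27 (HSP27, encoded by Hspb1) as a transgene, both male and 6 weeks old. The labels do not say whether a sample holds RNA of 1 animal or of a pool. Per the labels, total RNA was extracted with Trizol, and amplified complementary RNA was labelled with Cy3.

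Per the file headers, each deposited array file holds fluorescence intensity per spot from Agilent Feature Extraction version 11.5.1.1. The processed signal used here had its background subtracted and spatial and multiplicative trends removed by that software, with no normalization between arrays. The other columns used, per the file headers, are flags for spots well above background, saturated or outlying. The deposited table of the whole series is also an intensity on a linear scale. For each array, 39030 probes with 1 spot equalled the processed signal within 0.1%. Both arrays lay on the same slide and came from the same scan, so that slide and scan did not differ between the groups.

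Control spots and outlier spots were left out. Signals were taken to log2, spots of a probe were averaged, and each array was scaled by subtracting its 75th percentile over all non-control probes. A probe was used if it was well above background in at least 50% of its spots and unsaturated on both arrays. A gene's value was the mean over its usable probes. The files hold no gene name column, so the RefSeq accession of each probe was matched without version to a gene table of assembly GRCm38.p6. The array headers name another assembly, mm9, so the table served for names and for the span of genes alone, and no positions are given. Of 39429 probes, 27508 (69.8%) had a gene symbol, for 20886 symbols. There were 26387 usable probes, and 15495 genes were measured on both arrays, 4073 of them by more than 1 usable probe. In 22 genes, probes differed by at least 1.5-fold in opposite directions. A gene well above background on 1 array alone has a bound: the brighter value against the higher of the lowest signal well above background on the other array and the dim probe's own signal.

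With 1 array per group there was no spread between animals and no test between groups, and no p-value is given. Differences are the transgenic array minus the C57BL6/N array on the log2 scale, and counts are of genes past 2-fold or 1.5-fold. The technical spread came from probes printed in 10 spots. The SD of a difference between single spots was 0.17 for the dimmest, 0.09 for the middle and 0.08 for the brightest of 3 equal groups of 105 probes. This spread says nothing about variation between animals.

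Before the data were examined, 47 gene lists were fixed. The median difference of each list was set against 10000 random lists matched on mean signal in 20 bins. A percentile among random lists describes where the list lies among genes of these arrays and is no test of the groups. Lists share some members. Named genes followed a rule fixed at the same time. It took Hspb1 and the 12 largest differences per direction among genes with a recognised name, probes of 1 direction and a brighter value above the 25th percentile. It added up to 2 highest and 2 lowest members per list past 1.5-fold, 23 fixed genes of fibrosis, alveolar cells and inflammation, and the 5 largest bounds per direction. Of the genes so named, 2 are not reported here. The steps were tested on simulated data for the transgenic against C57BL6/N comparison, over 15495 genes. Genes simulated at 2-fold had a median log2 difference of 0.99, those at 4-fold 2.01. Of genes simulated at 2-fold, 40% passed 2-fold, and of those at 1.5-fold, 48% passed 1.5-fold, as the thresholds equal the simulated values. Of unchanged genes 0.0588% passed 1.5-fold under technical noise alone, which is no rate of false calls for this comparison, since no spread between animals was simulated.

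The alternatives chosen in advance were normexp background correction with an offset of 50, median scaling, quantile normalization, cyclic loess, no filter on dim probes, a stricter one, outlier spots kept, the brightest probe per gene, the deposited table, unmatched random lists, and the mean of a list. Normexp was planned on mean pixel signals. The files hold medians alone, so median signals and local background medians were used. That fit failed on the transgenic array, where 6 spots had a local background at or above their signal (highest background 217431, median 33.5). A normexp fit without such spots on either array was added after the data were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp and cyclic loess.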

Results

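Gene expression was measured in whole lung 14 days after bleomycin, a drug that injures the alveoli and leads to scarring when given into the airways. The series title names the question, the effect of HSP27 overexpression in this model of pulmonary fibrosis. HSP27 is a small heat shock protein that acts as a chaperone and binds actin filaments. There was 1 array of C57BL6/N lung and 1 of HSP27 transgenic lung, both after bleomycin at 1.25 mg/kg, and no array of untreated lung. Of 39429 probes, 27308 (69.3%) were well above background on the C57BL6/N array and 27378 (69.4%) on the transgenic array. The 75th percentile of signal was 1287 and 1426, and no spot was saturated. There were no replicates, so no difference below could be set against the spread between animals, and the number of arrays limits the precision.

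Among genes with a symbol, more had large differences upward than downward in the transgenic lung. Of 15495 genes measured on both arrays, 591 (3.81%) were at least 2-fold higher in the transgenic array and 289 (1.87%) at least 2-fold lower. At 1.5-fold, 1582 were higher and 1287 lower. At 16-fold, 26 were higher and 0 lower. The balance was the opposite among 6027 usable probes without a gene symbol, of which 158 were at least 2-fold higher and 411 at least 2-fold lower. Genes well above background on the transgenic array alone numbered 504, of which 195 had a bound of at least 2-fold. On the C57BL6/N array alone there were 330, of which 94 had such a bound. Genes with a negative bound or with probes in both directions were left out of these counts. Higher genes made up 67.2% of those past 2-fold, against 77.3% after cyclic loess, and 55.1% of those past 1.5-fold, against 66.5%. The 2-fold counts depended on the treatment of dim probes and background. They were 1195 higher and 736 lower without the filter on dim probes, 383 and 185 with a stricter filter, and 306 and 112 with a normexp correction without spots whose local background exceeded their signal, chosen after seeing the data. Normexp on all spots, whose fit failed on the transgenic array, gave 6312 and 737. The 1.5-fold counts were 2526 higher and 2080 lower without the filter, 980 and 682 with the added normexp, and 7791 and 2927 with the failed fit.

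Hspb1 itself was bright on both arrays. Its single probe read 41040 on the C57BL6/N array and 53554 on the transgenic array, a log2 difference of 0.24 (1.18-fold) after scaling. The repeat-spot SD was 0.08, which is technical spread alone. Over all measured genes the central 95% of differences ran from -0.92 to 1.24, so that a difference of 0.24 was not unusual. With the planned normexp, whose fit failed on the transgenic array, Hspb1 was at -0.58. The labels do not give the species of the transgene, so this mouse probe may not report it. Among 24 measured heat shock proteins and co-chaperones, 2 were at least 1.5-fold higher and 1 lower, with a median of -0.12 inside the central 95% of random lists (-0.19 to 0.12). Hspb7, a small heat shock protein abundant in striated muscle, was higher by 2.07 and Hspb6 by 0.63, while Hsph1, a cofactor of HSP70, was at -0.89.

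**Figure D1:**
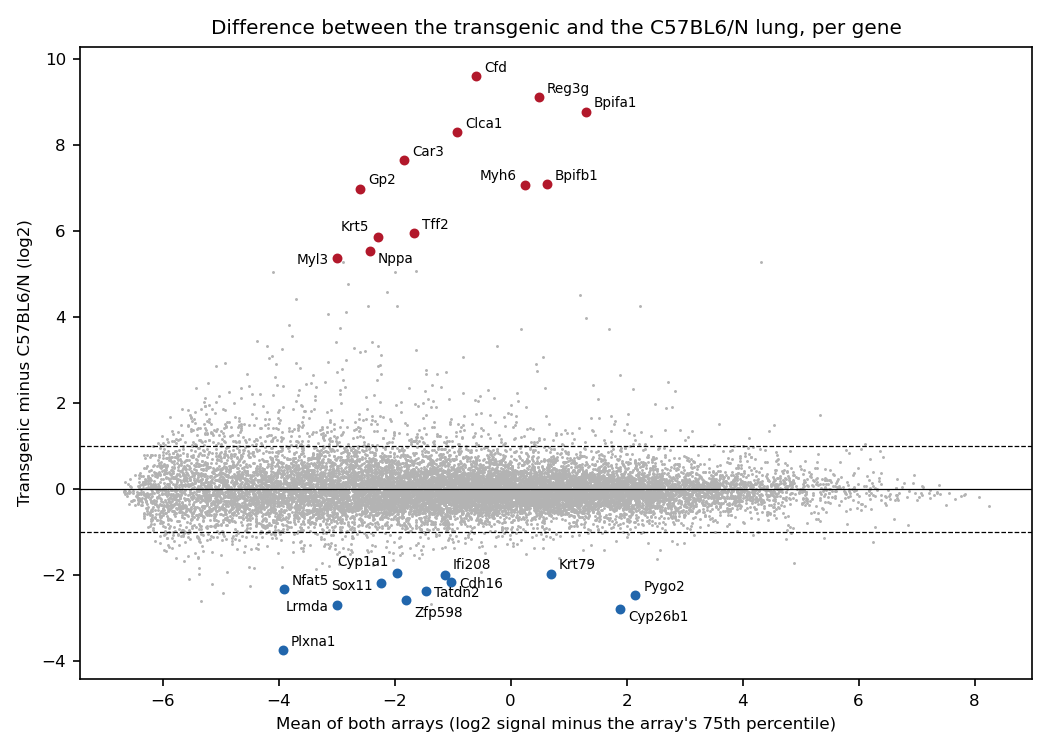
Each grey point is 1 of 15495 genes, with the mean of both arrays on the x axis (log2 signal minus the 75th percentile of the array) and the transgenic minus C57BL6/N difference (log2) on the y axis. Dashed lines mark 2-fold, and the 12 largest differences per direction that met the naming rule are coloured and labelled, from Cfd at 9.62 to Plxna1 at -3.76.

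Genes of the fibrotic matrix were higher in the transgenic lung. Of 18 measured collagens, 11 were at least 1.5-fold higher and 0 lower, and the median difference was 0.78, above the random range of -0.21 to 0.15. Type I collagen chains, the main fibre of scar tissue, differed by 0.80 for Col1a1 and 0.88 for Col1a2, and the type III chain Col3a1 by 0.32. Col5a3 (1.73) and Col5a1 (1.25), chains of the type V collagen that co-assembles with type I, had the largest differences of the list. Among 32 matrix glycoproteins and crosslinking enzymes, 17 were at least 1.5-fold higher and 2 lower (median 0.61). Elastin (Eln) was at 1.71, thrombospondin 2 (Thbs2) at 1.56 and fibronectin (Fn1) at 0.74, whereas P4ha1, a collagen prolyl hydroxylase, was at -0.84 and Fbln5, an elastic fibre protein, at -0.78. Of 20 matrix metalloproteinases and inhibitors, 13 were higher and 0 lower (median 0.71). Timp1, an inhibitor of these proteases, was 5.64-fold higher, Adamts4 was at 1.96 and Mmp12, the macrophage elastase, at 1.11. On the same array, markers of cardiac muscle (median 2.45), adipose tissue (2.15) and basal airway cells (1.34) were higher too.

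Markers of matrix-producing and contractile cells were higher as well. Fibroblast and myofibroblast markers had a median of 0.84, with 14 of 24 at least 1.5-fold higher and 0 lower. Grem1, an antagonist of bone morphogenetic proteins, was at 2.54, Cthrc1, a marker of activated fibroblasts, at 1.92, and Acta2, the smooth muscle actin of myofibroblasts, at 1.51. Smooth muscle and pericyte markers had a median of 0.41 (6 of 14 higher, 0 lower), with Actg2 at 1.64 and Rgs5 at 1.27. These cell markers stood beside higher medians of cardiac muscle (2.45), adipose (2.15) and basal cell (1.34) markers on that array. Genes of the TGF-beta pathway had a median of 0.05, inside the random range of -0.21 to 0.13, with 3 of 23 higher and 2 lower, among them Tgfbi at 0.74, Smurf2 at -0.71 and Skil at -0.59. Tgfb1 differed by 0.44 and Ccn2, a matricellular protein induced by TGF-beta, by 0.22. Factors and markers of epithelial-to-mesenchymal transition had a median of -0.05 over 10 genes, with Snai1 at 0.82, Tcf4 at -0.65 and Vim at 0.11. Epithelial junction and identity genes had a median of 0.05 over 20 genes, with Cldn4 at 1.13, Krt8 at 0.96, Tjp1 at -0.69 and Cdh1 at -0.18.

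**Figure D2:**
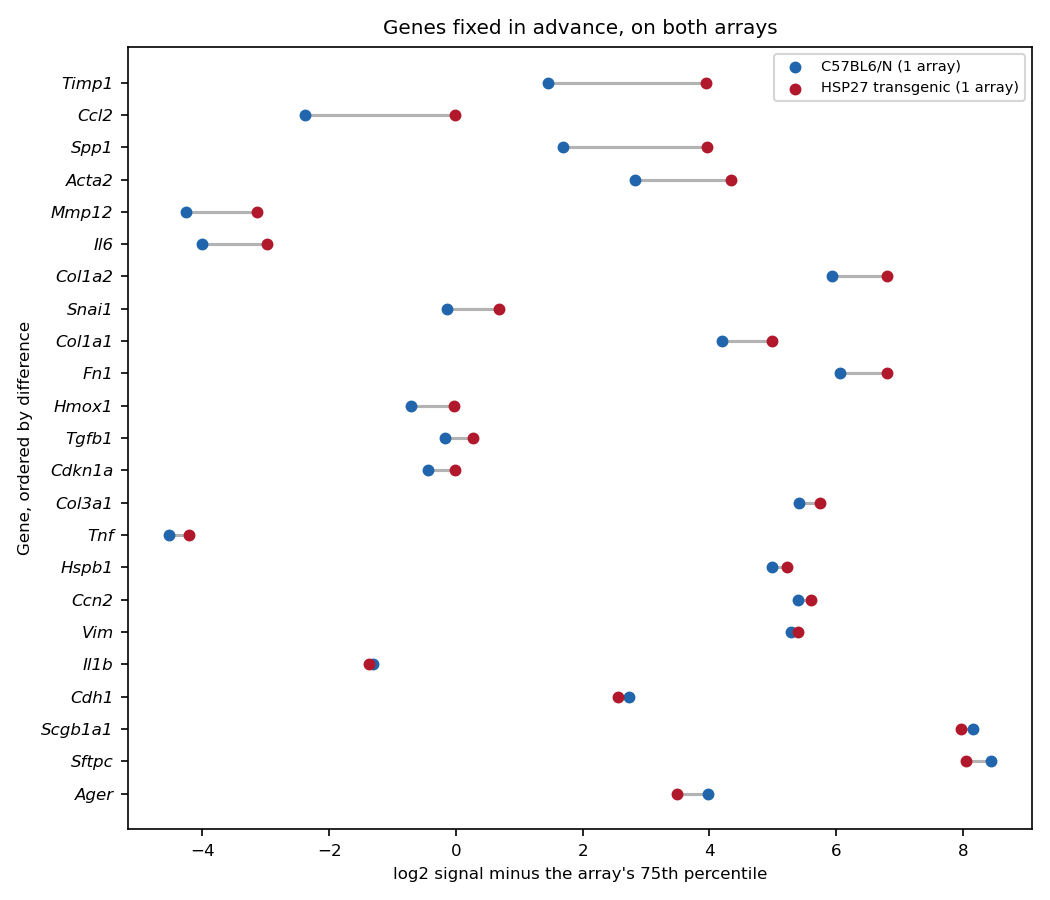
Of the genes fixed in advance, 23 are shown on both arrays, 1 array per group, as log2 signal minus the 75th percentile of the array. Lines join the C57BL6/N value (blue) and the transgenic value (red) of each gene, from Timp1 (5.64-fold higher) at the top to Ager (-0.49) at the bottom.

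Endothelial and alveolar type 1 markers were lower in the transgenic lung. Of 23 endothelial markers, 14 were at least 1.5-fold lower and 0 higher, with a median of -0.66 against a random range of -0.19 to 0.12. Tie1, an endothelial receptor kinase, was at -1.10 and Cldn5, the main claudin of vascular tight junctions, at -1.02. Of 16 alveolar type 1 cell markers, 8 were lower and 0 higher (median -0.59). Vegfa and Cav1 were both at -1.08, and Ager, the receptor that marks these thin gas-exchange cells, was at -0.49. Alveolar type 2 cell markers, from the cells that make surfactant, had a median of -0.26 with 2 of 19 higher and 1 lower, below the random range except with quantile normalization. Surfactant protein C (Sftpc) was at -0.40 and Hc at -0.76. Scd1 and Dlk1, members also known from fat or airway cells, were at 0.92 and 1.56. Markers of transitional alveolar epithelium, the keratin-rich state seen after alveolar injury, had a median of 0.48 with 8 of 19 higher and 1 lower. Sprr1a was at 1.43, Tnip3 at 1.22 and Areg at -0.67. The lower medians, like the higher ones, stood beside those of cardiac muscle (2.45), adipose (2.15) and basal cell (1.34) markers on the same array.

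Genes of the conducting airways were among those with the largest differences upward. Club and goblet cell markers had a median of 3.08 (8.47-fold), with 11 of 17 at least 1.5-fold higher and 0 lower. Reg3g, an antibacterial lectin, was 559-fold higher, Bpifa1 441-fold, the goblet cell product Clca1 318-fold and Bpifb1 137-fold. Gp2 (6.99) and the trefoil factor Tff2 (5.96) were also among the 12 largest. Scgb1a1, the main secretory protein of bronchiolar club cells, was at -0.19. All 6 measured basal cell markers, of the progenitors beneath the airway epithelium, were at least 1.5-fold higher (median 1.34), with Krt5 at 5.87 and Krt14 at 3.57. Ciliated cell markers had a median of 0.46 (8 of 26 higher, 0 lower), with Dnah5 and Sntn both at 0.94.

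Transcripts of heart muscle and fat were high on the transgenic array in parallel. The cardiac list was fixed to mark carried-over tissue or the muscle of pulmonary veins, and these sources were not told apart. Of 18 cardiac muscle markers measured on both arrays, 14 were at least 1.5-fold higher and 1 lower (median 2.45), and 5 more were well above background on the transgenic array alone. The atrial natriuretic peptide Nppa was at 5.55, the myosin chains Myh6 at 7.09 and Myl3 at 5.38, and Myh7 at -0.97. Sln was at least 283-fold higher, Mb, the muscle oxygen carrier, at least 106-fold, and Ckmt2 at least 49.4-fold. Adipose tissue markers had a median of 2.15, with 5 of 6 higher, 0 lower and 5 more on the transgenic array alone. Cfd (adipsin), made by fat cells, had the largest difference measured, 787-fold, with Retn at 5.27. Adipoq was at least 76.1-fold and Pck1 at least 54.0-fold higher. Car3, an enzyme abundant in muscle and fat, was 201-fold higher. Skeletal muscle markers had a median of 0.14 (3 of 10 higher, 0 lower), with Tnnt3 at 2.82 and Acta1 at 2.03. Markers of thymus, thyroid and oesophagus had a median of 0.05 over 7 genes, with Krt13 at 1.38 and Tg at 0.60.

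**Figure D3:**
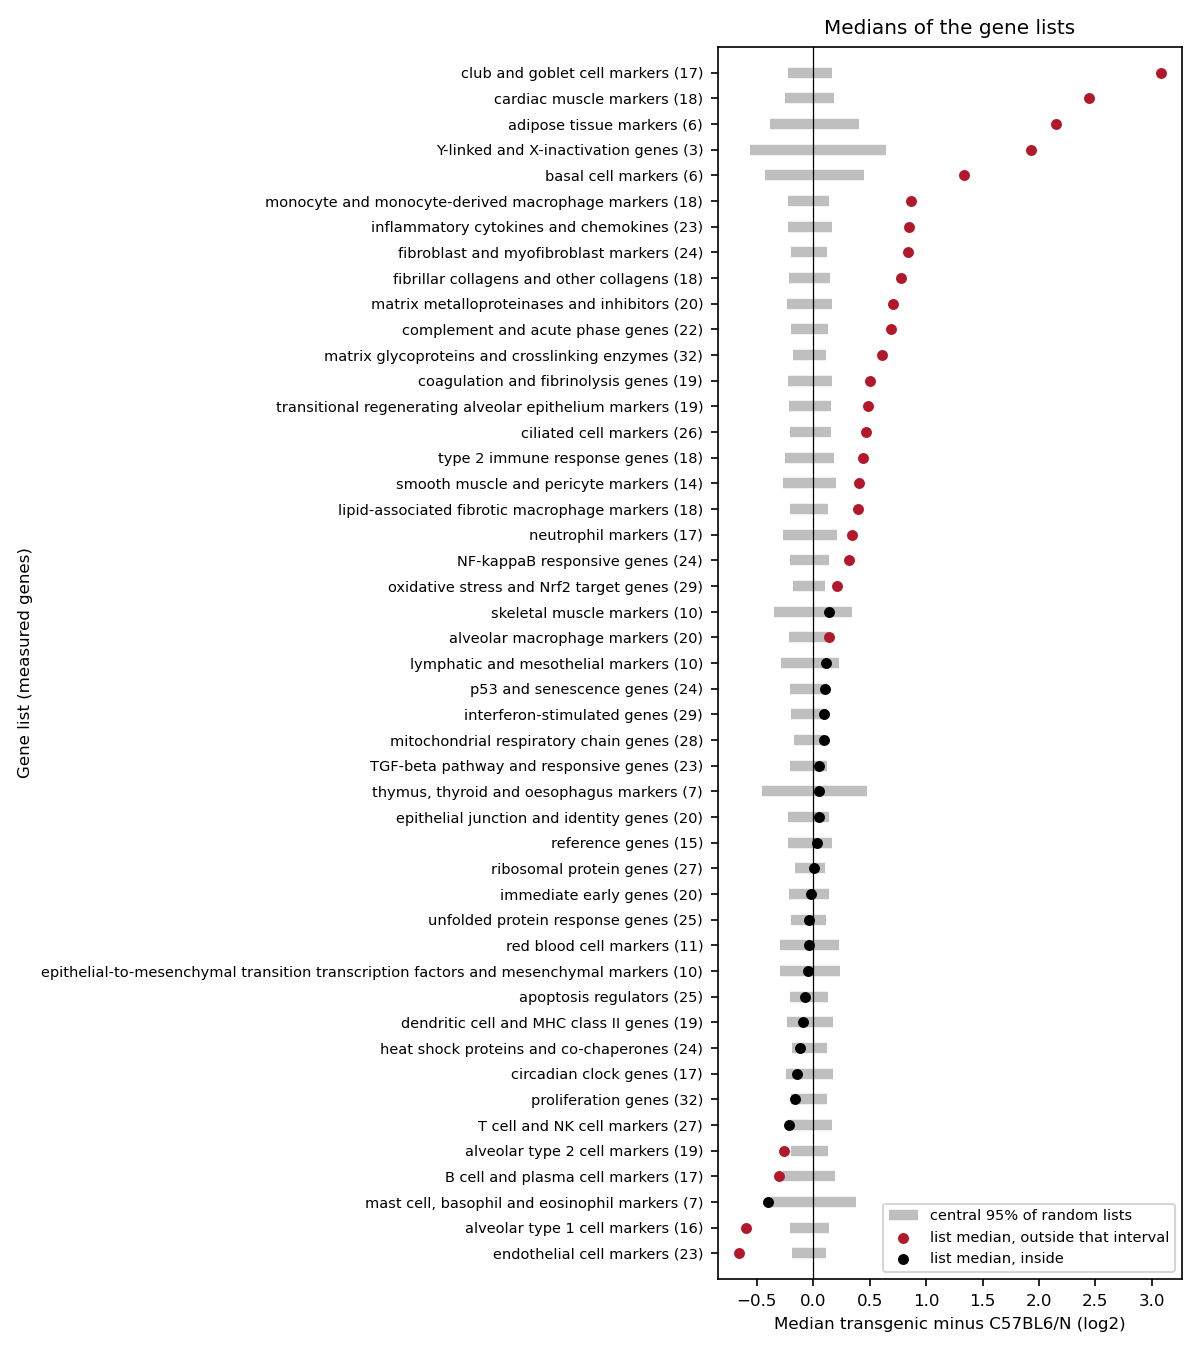
Points are the median transgenic minus C57BL6/N difference (log2, x axis) of each of 47 gene lists (y axis, with the number of measured genes), and grey bars span the central 95% of 10000 random lists matched on signal. Red medians lie outside the bar, 22 above it and 4 below it.

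Several lists of inflammatory genes had medians above the random range. The lists of T and NK cell markers and of B and plasma cell markers had medians below 0. That of T and NK cells lay inside its random range in the main processing. Monocyte and monocyte-derived macrophage markers had a median of 0.86 (13 of 18 higher, 0 lower), with the complement subunits C1qb at 2.41 and C1qa at 1.74. Lipid-associated fibrotic macrophage markers had a median of 0.39 (7 of 18 higher, 0 lower). Arg1 was at 2.35 and osteopontin (Spp1) 4.88-fold higher. Inflammatory cytokines and chemokines had a median of 0.85 (13 of 23 higher, 1 lower), with Saa3 at 3.73, the B cell attractant Cxcl13 at 2.72, the monocyte attractant Ccl2 at 2.37, Il6 at 1.03 and Ccl5 at -0.67. Il1b was at -0.07 and Tnf at 0.31. Complement and acute phase genes had a median of 0.69 (14 of 22 higher, 1 lower), with Saa1 at 2.91 and C7 at -0.93. NF-kappaB responsive genes had a median of 0.32 (5 of 24 higher, 1 lower), with Cxcl5 at 1.64, Cxcl1 at 1.40 and Traf1 at -0.75. Type 2 immune response genes had a median of 0.44 (8 of 18 higher, 3 lower), with the eosinophil attractant Ccl11 at 1.75, Chia1 at -1.42 and Il13ra2 at -1.13. The higher inflammatory medians also stood beside those of cardiac muscle (2.45), adipose (2.15) and basal cell (1.34) markers.

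Neutrophil markers had a median of 0.34 (7 of 17 higher, 2 lower). Ltf, also made by airway glands, was at 4.51, Mmp8 at 1.22, Cxcr2 at -1.28 and Ngp at -0.59. Alveolar macrophage markers went both ways, with 2 of 20 higher and 5 lower and a median of 0.14, above the random range except with both normexp corrections and with unmatched random lists. Fabp4, also a fat cell gene, was at 2.32, while Krt79 was at -1.97 and Fabp1 at -1.41. T cell and NK cell markers had a median of -0.22, with 2 of 27 higher and 7 lower, inside the random range of -0.23 to 0.17 but below it in 3 of the 10 alternatives and with unmatched random lists. Gata3 and the NK cell receptor Ncr1 were both at -1.32, whereas Foxp3, the factor of regulatory T cells, was at 0.98 and Ctla4 at 0.68. B cell and plasma cell markers had a median of -0.31 (0 of 17 higher, 3 lower), with Blk at -0.87. This median lay below the random range except with the stricter filter (percentile 6.00) and with normexp on all spots (17.1, Blk at 2.52).

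The largest differences downward were smaller. Plxna1, a semaphorin receptor, was 13.5-fold lower in the transgenic lung and Cyp26b1, an enzyme that degrades retinoic acid, 6.92-fold lower. Lrmda (-2.70), Zfp598 (-2.60), Pygo2 (-2.48), Tatdn2 (-2.38), Nfat5 (-2.33) and Cdh16 (-2.17) each rested on 1 usable probe. So did Plxna1, Cyp26b1 and Cyp1a1, and each of the 12 largest differences upward. Plxna1 read 25.4 on the transgenic array, where the lowest signal well above background was 12.5. Sox11 was at -2.20 over 2 probes and Ifi208, an interferon-inducible gene, at -2.01 over 4 probes, from -2.50 to -1.24. Cyp1a1, a target of the aryl hydrocarbon receptor, was at -1.95. With the planned normexp, whose fit failed on the transgenic array, direction turned for Plxna1, Lrmda, Zfp598, Tatdn2, Nfat5, Sox11 and Cyp1a1. Among genes well above background on the C57BL6/N array alone, the largest bounds after Xist were Afm (at least 3.70 on the log2 scale), Arsj (3.39), Olfr1186 (2.88) and Nudt16l2 (2.81).

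Sex-linked transcripts differed between arrays that were both labelled male. Xist, the RNA that coats the inactive X chromosome of female cells, read 521 and 330 at 2 probes on the C57BL6/N array and was not well above background on the transgenic array, at least 36.8-fold lower. The Y-linked genes Ddx3y (2.11), Eif2s3y (1.91) and Uty (1.93) were higher in the transgenic array, where the C57BL6/N signal was 23.1%, 26.5% and 26.2% of it after scaling. The Uty probe read 17.1 on the C57BL6/N array, where the lowest signal well above background was 11.9. Another Uty probe (at least 2.87-fold higher) and the Y-linked Kdm5d (at least 1.03-fold) were well above background on the transgenic array alone. The sex-linked difference stands beside every gene group above and below, since sex-linked transcripts and the transgene differed between the same 2 arrays.

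**Figure D4:**
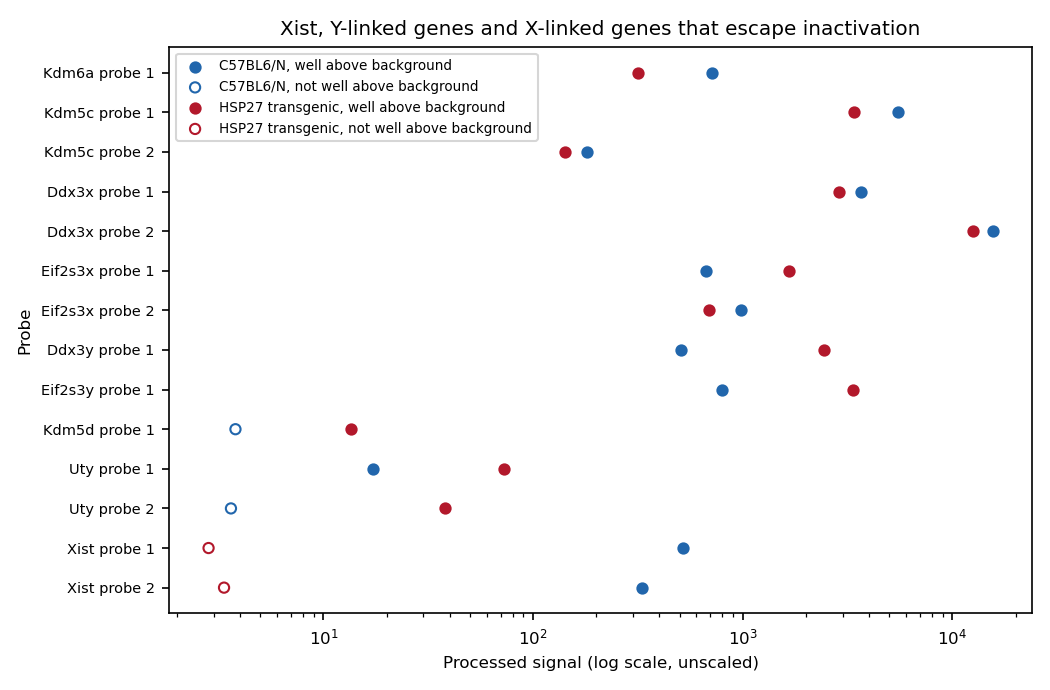
Processed signal (log scale, x axis) of each probe (y axis) for Xist, Y-linked genes and X-linked genes that escape inactivation, on the C57BL6/N array (blue) and the transgenic array (red). Open circles are not well above background, as for both Xist probes on the transgenic array.

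Genes of general cellular programmes were compared last. Ribosomal protein genes had a median of 0.00 over 27 genes, reference genes 0.03 over 15, with Gusb at 0.96 and Gapdh at 0.90, and nuclear genes of the mitochondrial respiratory chain 0.09 over 28, with Cyc1 at 0.63. Oxidative stress and Nrf2 target genes had a median of 0.21 (6 of 29 higher, 0 lower), with the glutathione transferase Gsta4 at 0.79 and haem oxygenase 1 (Hmox1) at 0.68. Coagulation and fibrinolysis genes had a median of 0.50 (7 of 19 higher, 1 lower), with Serpine2 at 1.56, F13a1 at 1.30 and thrombomodulin (Thbd) at -0.79, and the median was 0.33 with the added normexp. Both lists lay above the random range, on the array where cardiac muscle (2.45), adipose (2.15) and basal cell (1.34) markers were higher. Proliferation genes had a median of -0.17 over 32 genes, with Mki67 at -0.77 and Cenpa at 0.60. Genes of p53 signalling and senescence had a median of 0.11 over 24 genes, with Igfbp3 at 0.90 and Cdkn1a at 0.41.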

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

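All tests in this part were chosen after the results were seen, except the 2 tests of gene length. Of 6027 usable probes without a gene symbol, 158 were at least 2-fold higher in the transgenic array, a signal in data that the comparisons by gene do not use, and 411 were at least 2-fold lower, with log2 differences from -2.53 to 6.84.

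The first pattern was Xist signal and low Y-linked signal on the C57BL6/N array, although both samples were labelled male. RNA of female animals in that sample is a candidate explanation and stays open. X-linked genes that escape inactivation (Kdm6a, Kdm5c, Ddx3x and Eif2s3x) had a median difference of -0.57, just below the central 95% of random lists of X-linked genes (-0.53 to 0.39), but 2 of 4 lists with 1 gene left out lay inside their interval, and the probes of Eif2s3x were at 1.17 and -0.65. Whether that RNA was all female, with Y-linked probes reading X-linked homologues, or mixed with male RNA cannot be told apart, since 3 Y-linked genes with a range of 0.20 are too few. The labels name no pool, and no biological explanation was tested for this pattern.

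The second pattern was airway, cardiac muscle and fat transcripts on the transgenic array, with signals of 19725 for Myh6 and 26422 for Cfd. A mucous response of the airway epithelium alone leaves the muscle and fat transcripts unaccounted for. The lists fixed in advance had medians of 2.45 for cardiac muscle and 2.15 for adipose tissue, above their random intervals. These lists had already shown the pattern, so their medians restate it and are no separate test. For the airway transcripts a mucous response cannot be told apart from carried-over airway, because both raise the 8 mucous cell genes (median 4.66). Tissue around the main bronchi carried into the transgenic sample cannot be told apart from other sources, among them pulmonary vein muscle for the muscle transcripts. The reason is that 4 cartilage genes listed before their values were seen went both ways (median -0.19, random interval -0.59 to 0.69). These were Sox9 at 1.52, Col9a2 at 0.27, Col11a2 at -0.65 and Hapln1 at -0.98. Col11a1 (at least 3.55-fold higher) and Snorc (at least 1.64-fold) were well above background on the transgenic array alone. Matn1, Matn3, Cnmd, Col9a1 and Col9a3 were well above it on neither array. The measured cartilage genes seen first were higher (Col2a1 at 1.95, Comp at 1.49 and Acan at 0.86). With these included, 7 measured cartilage genes had a median of 0.86, above the random interval of -0.49 to 0.51. Since some had been seen first, that median is no separate test. The transgene stays open too, as untested.

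The third pattern was matrix genes higher and endothelial and alveolar type 1 genes lower in the transgenic array. Dilution by carried-over tissue alone would lower all lung cell types alike if that tissue held none of their markers. Alveolar type 2 markers lay 0.40 above endothelial markers (95% interval 0.19 to 0.67, resampling genes, which are not independent). Without 7 members known from fat or airway (Scd1, Fasn, Dlk1, Muc1, Lyz1, Cxcl15 and Chil1), the difference was 0.25 (0.062 to 0.57). Alveolar type 1 minus endothelial was 0.07 (-0.28 to 0.34). For endothelial against alveolar type 2 genes, the differences of 0.40 and 0.25 argue against dilution alone by tissue that held none of these markers. The alveolar type 1 difference of 0.07 does not. Whether carried-over tissue held some of these markers was not tested, so dilution by such tissue is not excluded. For the higher matrix genes (collagen median 0.78), carried-over connective tissue cannot be told apart from scarring, since both hold these collagens. A trend with gene length, from a median of 0.04 in the shortest of 4 equal groups of genes to -0.15 in the longest, is argued against as the whole cause, since the difference from length-matched lists was -0.62 for endothelial and 0.90 for collagen genes, though gene span is not transcript length and RNA quality itself was not tested. A difference between single animals or between the sexes could account for this pattern as well as the transgene, and with 1 array per group these cannot be told apart.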

How the results depend on the processing

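The normexp fit without failed spots was added after the data were seen, and the other alternatives were planned. Each group had 1 array, so no array could be left out, and no paired analysis was possible because each group had 1 sample. Signal over background limits the dim probes. Among 148 named genes measured on both arrays, 0 of those past 1.5-fold turned direction in the 9 alternatives other than the planned normexp. Those alternatives process the same 2 arrays and kept the median of all genes between -0.056 and 0.028, so such a turn was unlikely. Some of the 148 genes had no value with the stricter filter. Of 26 lists outside the random interval, 23 stayed outside on the same side in those 9 alternatives, and 17 in all 10. Of the others, 3 moved inside it in alternatives other than planned normexp: alveolar type 2 (percentile 2.85 with quantile normalization), B cells (6.00 with the stricter filter) and alveolar macrophages (96.9 with the added normexp). Planned normexp moved 6 more inside it: transitional epithelium (percentile 93.2), ciliated (71.4), basal (91.4), neutrophil (94.5), NF-kappaB (68.9) and type 2 immune response (93.0). Of 21 lists inside the interval, 6 lay outside it in at least 1 alternative: T and NK cells in 3 (percentile 1.15 without the filter on dim probes), respiratory chain in 3 (99.8 with the brightest probe), p53 and senescence in 2 (99.5 without the filter on dim probes), epithelial junction in 1 (99.4 with the brightest probe), mast cells in 5 (0.15 with the added normexp) and interferon in 1 (98.7 with the added normexp). Median scaling, outlier spots kept and the deposited table left all 4 counts within 1.5 times and all 47 list medians within the SD of random lists. Unmatched random lists moved 3 of 47 lists across an end of the interval, alveolar macrophages to inside it (percentile 94.9) and T and NK cells (2.45) and mast cells (2.20) to below it. The cause was not tested except where named.

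Planned normexp set the median signal of the transgenic array at 11.08 (log2) against 8.13, while without failed spots the medians were 7.64 and 7.56, so the planned fit on the transgenic array was carried by those spots. It moved the median of all genes to 0.60, so list medians under it are not comparable in size with the main ones, and gave 6312 higher and 737 lower genes at 2-fold, 7791 and 2927 at 1.5-fold, and Hspb1 at -0.58. Direction turned for Plxna1 at 1.12, Lrmda at 0.92, Zfp598 at 0.33, Tatdn2 at 0.21, Nfat5 at 1.54, Sox11 at 0.50, Cyp1a1 at 0.69, Col1a1 at -0.0027, Fn1 at -0.072, Tgfbi at -0.11, Hba-a1 at -0.21, Cyc1 at -0.13, Fabp1 at 0.62 and Ncr1 at 2.31. It also turned for Cxcr2 at 1.37, Il13ra2 at 2.36, Per3 at 1.41, C7 at 0.16, Blk at 2.52, P4ha1 at 0.72, Siglecf at 0.73, Ern1 at 0.32, Fbln5 at 0.47, Car1 at 1.61, Cd209a at 1.24, Skil at 0.068, Ngp at 2.52 and Fasl at 2.07. Among list medians, it put heat shock at -0.41, collagens at 0.16, matrix glycoproteins at 0.46, fibroblasts at 0.12, smooth muscle at 0.94, TGF-beta at -0.15, mesenchymal transition at 0.21, epithelial junction at -0.28, metalloproteinases at 0.96, alveolar type 2 at -0.94, alveolar type 1 at -1.22, transitional epithelium at -0.027, club and goblet at 2.47, ciliated at 0.84 and basal at 2.13. It further put endothelial at -1.18, lymphatic and mesothelial at 0.34, alveolar macrophage at -0.26, monocytes at 0.32, lipid-associated macrophages at -0.23, neutrophil at 1.37, T and NK cells at 1.34, B cells at 0.85, mast cells at 1.58, dendritic cells at 0.32, NF-kappaB at 0.54, cytokines at 1.80, type 2 immune response at 1.004, interferon-stimulated at 0.38 and p53 and senescence at -0.33. It also put proliferation at 0.28, Nrf2 targets at -0.28, unfolded protein response at -0.48, apoptosis regulators at 0.069, circadian clock at 0.35, skeletal muscle at 2.14, adipose tissue at 1.92, thymus and thyroid at 2.13, red blood at -0.29, ribosomal protein at -0.84, reference at -0.55, respiratory chain at -0.69, complement and acute phase at 0.24 and Y-linked at 1.45.

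Without failed spots normexp gave 306 higher and 112 lower genes at 2-fold, of which 301 and 112 were shared with the main setting, and 980 and 682 at 1.5-fold. Among list medians, it put matrix glycoproteins at 0.46, fibroblasts at 0.69, metalloproteinases at 0.60, club and goblet at 2.79, ciliated at 0.37, basal at 0.96, neutrophil at 0.17, NF-kappaB at 0.22, cytokines at 0.54, type 2 immune response at 0.23, coagulation and fibrinolysis at 0.33 and cardiac muscle at 2.23. Without the filter on dim probes, 1195 were higher and 736 lower at 2-fold and 2526 and 2080 at 1.5-fold, with more genes measured (20878). This put mesenchymal transition at 0.14, club and goblet at 2.77, mast cells at -0.18, cardiac muscle at 3.33, adipose tissue at 4.40 and red blood at -0.22. The stricter filter left 12763 genes, 383 higher and 185 lower at 2-fold. It put smooth muscle at 0.76, mesenchymal transition at -0.21, mast cells at -0.67, dendritic cells at 0.060, NF-kappaB at 0.21, cardiac muscle at 3.31 and skeletal muscle at 0.54. Means put heat shock at -0.00036, matrix glycoproteins at 0.48, fibroblasts at 0.75, alveolar type 2 at -0.095, club and goblet at 3.50, ciliated at 0.37, basal at 2.37, alveolar macrophage at 0.0048, lipid-associated macrophages at 0.59, neutrophil at 0.48, dendritic cells at 0.038, cytokines at 1.04, interferon-stimulated at 0.22, skeletal muscle at 0.62, adipose tissue at 3.33, reference at 0.16 and complement and acute phase at 0.90. Cyclic loess put matrix glycoproteins at 0.70 and cytokines at 0.99. The brightest probe put smooth muscle at 0.57, mesenchymal transition at 0.12, epithelial junction at 0.18, dendritic cells at 0.060 and cytokines at 0.72.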

Other observations

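The gene lists fixed in advance that are given in this part had medians inside the central 95% of random lists in the main processing. The mast cell list lay below it in 5 of the 10 alternatives and with unmatched random lists, and the interferon list above it in 1. Interferon-stimulated genes had a median of 0.10, with 8 of 29 at least 1.5-fold higher and 1 lower, among them the chemokines Cxcl10 at 1.95 and Cxcl9 at 1.61, and Gbp3 at -0.64. Immediate early genes had a median of -0.02, with 3 of 20 higher and 4 lower, from Junb (1.46) and Myc (1.11) to Klf2 (-1.07) and Klf4 (-0.78). Dendritic cell and MHC class II genes had a median of -0.10, with H2-DMa at 0.94, Batf3 at 0.75 and Cd209a at -0.74. Mast cell, basophil and eosinophil markers had a median of -0.40 over 7 genes, with Siglecf at -0.83 and Kit at -0.73. Lymphatic and mesothelial markers had a median of 0.11 over 10 genes, with Wt1 at 0.83 and Lyve1 at -0.66.

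Unfolded protein response genes had a median of -0.03 over 25 genes, with Ern1, the sensor IRE1, at -0.82. Apoptosis regulators had a median of -0.07 over 25 genes, with Casp1 at 0.76, Xiap at -0.61 and Fasl at -0.59. Circadian clock genes had a median of -0.14 over 17 genes, with Nfil3 at 0.90 and Per3 at -1.08. Red blood cell markers had a median of -0.04 over 11 genes, with Hba-a1 at 0.69 and Car1 at -0.75. Chosen after their values were seen, 5 measured major urinary protein genes had a median of 4.76 in the transgenic array. They are close paralogs, and their probes were not checked for sharing targets. Bronchiolar secretory genes (Scgb1a1, Cyp2f2, Aldh1a7 and Cbr2), also chosen after their values were seen, had a median of 0.01. The ventricular muscle gene Myl2 was at -0.35.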
